A study of Mus musculus with 8 samples.

How the data were processed

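RNA sequencing of mouse testis was analysed from 8 libraries, 2 in each of the groups CTRL, LPS, LPS+DHEA and LPS+DHEA+Nb, as the labels' titles give them. The labels give a vehicle injection for CTRL, LPS for the other groups, and DHEA or DHEA with Nb23-bi 6 h after LPS. Doses, the time of tissue collection and whether the 2 libraries of a group come from separate animals are not given in the sources used here. The labels name testis as the tissue, while the extraction protocol speaks of islets, and the label's tissue was used. Germ cell transcripts such as Tnp1 at 1960.8 CPM in CTRL were among the abundant genes.

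Per the labels' protocols, the libraries were made with the KAPA Stranded RNA-Seq kit. Per the submitters' processing notes, the tools were HISAT, with no version, and featureCounts 1.5.0-p3 on GRCm38, with no role or order stated. The deposited values were taken to be estimated counts (expected counts) per Ensembl gene, not scaled for library size, in a separate file per library. The unit was read from the values. They were whole numbers, and of the values from 1 to 40, 33.5% were multiples of 4 where 25% would be even, while from 1000 to 10000 the share was 25%. The value 4 occurred 9737 times, 3 occurred 4602 times and 5 occurred 5075 times. Some overlapping genes differed in opposite directions between libraries, as with Gm49380 (1904 and 1776 in the LPS+DHEA+Nb libraries, 3 to 34 elsewhere) and Gm39325 (66 and 27 there, 1862 to 2294 in 5 of the others), both chosen after their values were seen. In CTRL 1 both were low, at 34 and 17. How the authors made the deposited values beyond these notes is not given in the sources used here, nor are the strand setting and the handling of reads with several matches. The tests had been planned for counts, and since the values were already whole they were used without rounding in the same tests. If each fragment were counted 4 times, the depth would be 15.3 to 16.1 M per library, so an alternative divided the counts by 4.

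Each library held 55421 gene identifiers, of which 55154 had a symbol and 55240 a position in GENCODE M21 (GRCm38). Coordinates are 1-based. Each library held 61.3 to 64.5 M counts. Bootstrap intervals of a list's median cover the spread between its genes.

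Genes were filtered with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total count 15), which kept 26414. Libraries were scaled by TMM, with factors of 0.985 to 1.015. A single quasi-likelihood model with 4 group means and 4 residual degrees of freedom was fitted to the 8 libraries (glmQLFit and glmQLFTest, robust), with a common biological coefficient of variation of 0.231. The p-values were adjusted by the Benjamini-Hochberg method over the genes tested in each of 6 comparisons, and a gene was called at an adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM values use the TMM-scaled library sizes. R 4.3.3 was used.

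30 gene lists, fixed before the data were examined, were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes and adjustment over the lists. Camera with an estimated correlation and fry were the alternatives. Lists needed at least 5 measured members. For lists called by camera, the counts of genes are given over all genes and adjusted over the list alone. The comparisons, tests, lists, rule for naming genes and most alternatives were chosen before the data were examined.

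The genes named come from a fixed rule for each of 4 comparisons. It takes up to 10 genes with the largest fitted change in each direction among called genes. These needed a symbol that is not of the Gm number, Rik or pseudogene kind, a mean of at least 1 CPM in the higher group, and both libraries of a group above both of the other. If none passed, it took the 3 with the smallest p in each direction, given as not passing. It adds up to 4 members per list with the smallest p, and 11 genes given whatever their result. The text uses a part of these, and the result of 1 of them is not reported here.

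Return of LPS-called genes was counted as genes called in the opposite direction in the treated group against LPS. Because both comparisons use the LPS libraries, 25 data sets with no effect and 25 with an LPS effect only were simulated.

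The steps were tested on simulated data with 200 of 25627 genes changed. For LPS versus CTRL, 89 genes were called, of which 12 were false, and 14.9% of genes changed by 1.5-fold, 32.8% by 2-fold and 68.2% by 4-fold were recovered. For LPS+DHEA+Nb versus LPS, 88 were called, of which 19 were false, and 7.5%, 34.3% and 62.1% were recovered. For LPS+DHEA versus LPS, simulated without changes, 3 genes were called.

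The alternatives were DESeq2 size factors or library size alone in edgeR, no filter on low counts, CPM of at least 1 in at least 2 libraries, DESeq2 1.42.0, limma-voom, only the 2 groups compared, the replicate number as a block, each library left out in turn, an adjusted p under 0.10, and a log2 fold change of at least 1. Division of counts by 4 and summing of overlapping genes on a strand were added after the data were seen. Calls of single genes were followed through 18 of these, which leave out the 2 changed thresholds. No library was left out of the analysis.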

Results

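The data are RNA-seq values per gene from mouse testis, taken to be estimated read counts, with 8 libraries in 4 groups of 2. The CTRL group received vehicle, and the other groups received lipopolysaccharide (LPS), a bacterial cell wall component that triggers inflammation through Toll-like receptor 4. The LPS+DHEA and LPS+DHEA+Nb groups were injected 6 h after LPS with dehydroepiandrosterone (DHEA), a precursor of androgens, or with DHEA and Nb23-bi, an agent that the labels name without describing. Each library held 61.3 to 64.5 M counts, with at least 1 count in 30142 to 30626 genes. The 10 most abundant genes took 3.37 to 3.68% of the counts, and mitochondrially encoded transcripts took 0.89 to 1.23%. The first principal component held 17.7% of the variance and set the CTRL (-49.7 and -41.4) and LPS+DHEA+Nb libraries (-16.8 and -36.5) on the negative side. The LPS (46.6 and 39) and LPS+DHEA libraries (31.6 and 27.1) lay on the positive side. The second component held 14.8% and parted libraries of the same group. Its values were 52.2 and -25.7 in CTRL, 26.4 and -40.5 in LPS, -2 and 16.9 in LPS+DHEA, and 25 and -52.3 in LPS+DHEA+Nb. Correlations between libraries were 0.9695 to 0.9711 within groups and 0.9662 to 0.9713 between groups, so libraries of a group were not clearly more alike. Values are given in CPM (counts scaled to the total of the library) as mean ± SD with n = 2 per group, and log2 fold changes with their standard errors (SE) and Benjamini-Hochberg adjusted p-values from edgeR. Whether the 2 libraries of a group come from separate animals is not given in the sources used here, so each SD, SE and p-value measures the spread between libraries. With 2 libraries per group, genes with moderate changes can be missed at this size. Some of the called genes can also be false. When the steps were tested on simulated data, 12 of the 89 genes called in LPS versus CTRL were false. In LPS+DHEA+Nb versus LPS, 19 of the 88 called were false. In both, false calls made up a larger share than the threshold on the adjusted p aims at.

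The comparison of LPS with CTRL asks which testis genes respond to LPS. Of 26414 genes tested, 68 rose and 10 fell after LPS. The risen genes included 8 of 25 on the acute phase list, 3 of 23 cytokines and chemokines, 5 of 20 genes of MHC class I and antigen processing, and Acta2 alone of 12 smooth muscle markers. With an estimated correlation none of these 4 lists passed (adjusted p = 0.0626, adjusted p = 0.0789, adjusted p = 0.068 and adjusted p = 0.0681). Saa3, an acute phase serum amyloid A protein, rose most among abundant genes, from 1.19 ± 0.417 CPM in CTRL to 137.6 ± 33.3 CPM in LPS (log2 fold change 6.85, SE 0.33, adjusted p = 0.00144). Saa3 lies on GRCm38 chromosome 7 from 46711998 to 46715700. Cp, which encodes the copper carrier ceruloplasmin, rose from 8.62 ± 0.58 to 44.8 ± 1.23 CPM (log2 fold change 2.38, SE 0.12, adjusted p = 1.64e-05). Lcn2, which encodes an iron-sequestering protein of the innate defence, rose from 126 ± 1.5 to 320.4 ± 9.34 CPM (log2 fold change 1.35, SE 0.12, adjusted p = 0.00218).

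The acute phase and injury list had 8 of 25 measured members higher and none lower at an adjusted p over all genes, and 18 higher when adjusted over the list alone. Its median log2 fold change was 1.35 (camera adjusted p = 5.21e-30, adjusted p = 0.0626 with an estimated correlation). Besides Saa3, Cp and Lcn2, the protease inhibitors Serpina3n (log2 fold change 3.85) and Timp1 (3.46) and the secreted glycoprotein gene Lrg1 (2.52) rose. Among inflammatory cytokines and chemokines, 3 of 23 rose, and adjusted over the list alone 10 were higher and 1 was lower (median 1.47, camera adjusted p = 1.39e-09, adjusted p = 0.0789 with an estimated correlation). The risen members included the chemokine genes Ccl7 and Cxcl13, which attract monocytes and B cells. Cxcl13 had 6 and 8 counts in the CTRL libraries and 235 and 199 in the LPS libraries. Ccl12, another monocyte chemokine, had 0 and 8 counts in CTRL and 184 and 110 in LPS. Il1b and Cxcl10 did not pass, with log2 fold changes of 0.38 (adjusted p = 0.944) and 0.96 (adjusted p = 0.683). Tnf, with 0 and 10 counts in CTRL and 11 and 9 in LPS, did not pass either (adjusted p = 0.949), and Il6 had too few counts to be tested. The list of NF-kB feedback and adhesion targets had 3 of 26 members higher, and 11 when adjusted over the list alone (median 0.56, camera adjusted p = 1.56e-13, adjusted p = 0.0625 with an estimated correlation). They were the leukocyte adhesion gene Icam1 (log2 fold change 2.08), the cytokine signalling inhibitor Socs3 (2.35) and Tnip1 (0.88), an inhibitor of NF-kB signalling.

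Among genes of MHC class I and antigen processing, 5 of 20 rose, and 14 were higher when adjusted over the list alone (median 0.67, camera adjusted p = 1.54e-15, adjusted p = 0.068 with an estimated correlation). H2-D1 (log2 fold change 1.27), H2-K1 (0.69), H2-Q4 (1.41) and the light chain gene B2m (1.03) were among them. The H2 genes are close copies of each other, so their separate values are uncertain. None of 46 interferon-stimulated genes passed over all genes, 4 were higher when adjusted over the list alone, and 43 had a positive fold change (median 0.67, camera adjusted p = 5.53e-17, adjusted p = 0.214 with an estimated correlation). In that list Gbp5, a guanylate-binding protein, had a log2 fold change of 1.21 (adjusted p = 0.166) and Stat2, a signal transducer of interferon, had 0.67 (adjusted p = 0.251). At an unadjusted p under 0.05 edgeR gave 1879 genes in this comparison, where 1321 would be expected by chance.

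Few markers of cell types passed over all genes after LPS, and none of these lists passed with an estimated correlation. Among neutrophil markers, 2 of 12 rose, Lcn2 and S100a8, and 7 were higher when adjusted over the list alone (median 3.9, camera adjusted p = 1.14e-08, adjusted p = 0.0681 with an estimated correlation). Members such as S100a9 (0 and 0.08 CPM in CTRL) and Clec4d (0.06 and 0.06) lay near 0 counts. The size of this median, and of the later medians of this list, therefore depends on the prior count of the fit. Against a floor of 3 counts per library, S100a8 rose at least 21.5-fold. S100a8, a calcium-binding protein of neutrophils, had 0 counts in both CTRL libraries and 81 and 49 in LPS (adjusted p = 0.0237). Its call ended with limma-voom, with counts divided by 4 and without either CTRL library. Among peritubular myoid and smooth muscle markers, 1 of 12 rose, and 8 were higher when adjusted over the list alone (median 0.48, camera adjusted p = 1.06e-09, adjusted p = 0.0681 with an estimated correlation). The risen gene was Acta2, smooth muscle actin, from 46 ± 0.964 to 98.3 ± 6.61 CPM (log2 fold change 1.1, SE 0.1, adjusted p = 0.000737), while Myh11 had 0.58 (adjusted p = 0.184) and was called without LPS replicate 1 (0.76) and with DESeq2. None of 18 endothelial markers passed alone and 2 were higher when adjusted over the list alone (median 0.5, camera adjusted p = 1.34e-05, adjusted p = 0.0681 with an estimated correlation). Marco, a scavenger receptor of macrophages, rose from 0.261 ± 0.06 to 5.2 ± 1.39 CPM (log2 fold change 4.31, SE 0.53, adjusted p = 0.0186). The list of monocyte and macrophage markers did not pass, with 10 of 24 fold changes positive, none past the threshold over all genes, and 1 higher and 2 lower adjusted over the list alone (median -0.14, camera adjusted p = 0.288). Cx3cr1 was at -1.35 (adjusted p = 0.133), Csf1r at -0.9 (adjusted p = 0.19) and Itgam, an integrin of myeloid cells, at 3.42 (adjusted p = 0.322), from 28 and 43 counts in CTRL to 583 and 176 in LPS. Mitochondrially encoded transcripts had a negative fold change in 13 of 13 (median -0.36, camera adjusted p = 1.9e-12, adjusted p = 0.214 with an estimated correlation), none passed over all genes and 7 were lower when adjusted over the list alone. Spermatid and sperm genes had a median of -0.06 (camera adjusted p = 0.00259, adjusted p = 0.386 with an estimated correlation), none passed over all genes and 1 was lower when adjusted over the list alone. The abundant members Tnp1 and Prm1, which package sperm DNA, had log2 fold changes of -0.27 (adjusted p = 0.116) and -0.25 (adjusted p = 0.323).

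Further lists called higher by camera included Toll-like receptor 4 signalling components (1 of 20 higher, 3 adjusted over the list alone, median 0.18, camera adjusted p = 0.00117, adjusted p = 0.0873 with an estimated correlation), where Tlr2, a receptor of bacterial lipoproteins, rose (log2 fold change 2.06). Glucocorticoid-responsive genes had 1 of 19 higher and 5 adjusted over the list alone (median 0.17, camera adjusted p = 1.61e-05, adjusted p = 0.115 with an estimated correlation). The cAMP and immediate early targets had none of 23 higher and 2 adjusted over the list alone (median 0.13, camera adjusted p = 0.00263, adjusted p = 0.214 with an estimated correlation). Tlr4, the LPS receptor, had 0.507 ± 0.219 CPM in LPS and 0.308 ± 0.016 in CTRL (log2 fold change 0.71, adjusted p = 0.914).

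Genes of Leydig cells, which make testosterone, did not pass as a list (median -0.03, camera adjusted p = 0.26), although 3 were higher and 5 lower when adjusted over the list alone. Cyp17a1, the enzyme that converts progestogens to androgens, had 130.5 ± 35.3 CPM in CTRL and 30.8 ± 18.9 in LPS (log2 fold change -2.08, SE 0.51, adjusted p = 0.491). Hsd3b1, a steroid dehydrogenase, had 59.1 ± 11.6 and 17.5 ± 7.54 CPM (log2 fold change -1.75, SE 0.32, adjusted p = 0.218). Insl3, a Leydig cell hormone, had 574.4 ± 32.3 and 559.7 ± 21.6 CPM, and Star, a cholesterol carrier protein, had 29.5 ± 5.06 and 31.8 ± 3.57 CPM. The luteinizing hormone receptor gene Lhcgr had a log2 fold change of -1.08 (adjusted p = 0.115). These results depend on single libraries and on the test. Cyp17a1 was called without LPS replicate 1 (-2.91), Hsd3b1 without LPS replicate 1 (-1.37) or 2 (-2.27) and Lhcgr without CTRL replicate 1 (-1.37), and all 3 were called with DESeq2. Adgrg2, an adhesion receptor that has been reported to bind DHEA, had 0.78 ± 0.245 CPM in CTRL and 0.94 ± 0.684 CPM in LPS (adjusted p = 0.987).

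**Figure D1:**
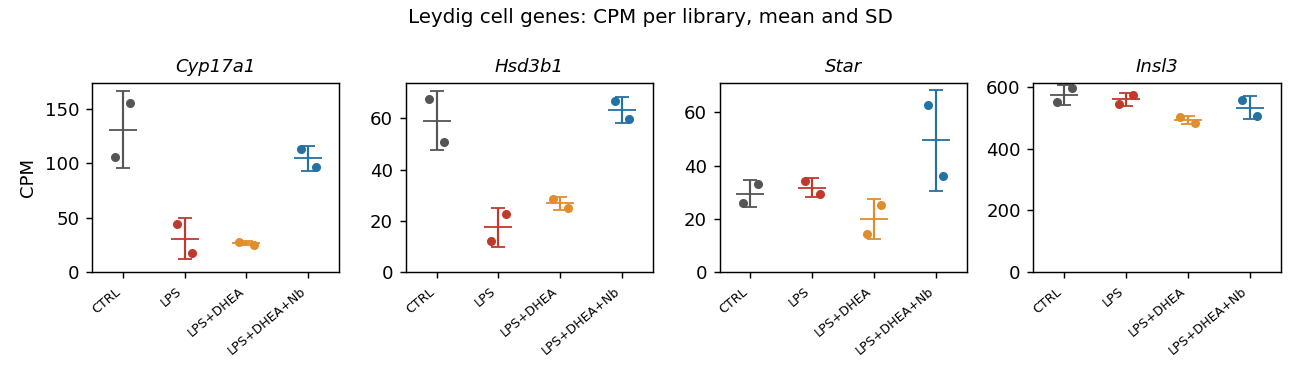
Normalised CPM of 4 Leydig cell genes per library (points), with the group mean and SD (bars), on linear axes that start at 0, with 2 libraries in each of the 4 groups. Cyp17a1 and Hsd3b1 sit lower in LPS and LPS+DHEA than in the other groups without passing the test (adjusted p = 0.491 and 0.218 in LPS versus CTRL), and Insl3 lies between 493.3 and 574.4 CPM in all group means.

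Of the fallen genes, Nupr1l, a gene related to the stress regulator Nupr1, went from 176.1 ± 7.69 CPM in CTRL to 59.4 ± 5.91 CPM in LPS (log2 fold change -1.57, SE 0.09, adjusted p = 1.77e-05). The fallen genes also included Ncoa4, a receptor of ferritin breakdown (-1.16), Arrb1, which encodes a beta-arrestin (-0.89), Ephx1, a detoxifying epoxide hydrolase (-0.78), and the germ cell RNA-binding gene Rbm44 (-0.51). Olfr273, of the olfactory receptor family, had 4 and 2 counts in CTRL and 121 and 208 in LPS. The remaining lists did not pass, at camera adjusted p-values of 0.101 to 0.828. These covered inflammasome, lymphocyte, Sertoli, spermatogonial, meiotic, epididymal, adipocyte and red blood cell genes. They also covered cholesterol synthesis, androgen-regulated genes, steroid receptors, the blood-testis barrier, apoptosis, oxidative stress and endoplasmic reticulum stress. Of the 30 lists, camera called 11 higher and 2 lower. No list kept its call with an estimated correlation, and fry, which tests whether a list's genes move on balance one way, called 7 lists. The count of 78 genes was 281 with DESeq2, 140 without a filter on low counts, 122 at an adjusted p under 0.10 and 118 without LPS replicate 1, and 33 of the 78 were called again without CTRL replicate 2 and 34 without CTRL replicate 1. Saa3, Cxcl13, Serpina3n, Timp1, Nupr1l, Ncoa4, Ephx1, Cp, Lrg1, Lcn2, Icam1 and Acta2 stayed called under each of 18 alternatives that keep the thresholds, while the calls of S100a8, Ccl12, Marco, Ccl7, Arrb1, Rbm44, Socs3, Tnip1, Tlr2 and the H2 and B2m genes each ended when 1 or more single libraries were left out.

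**Figure D2:**
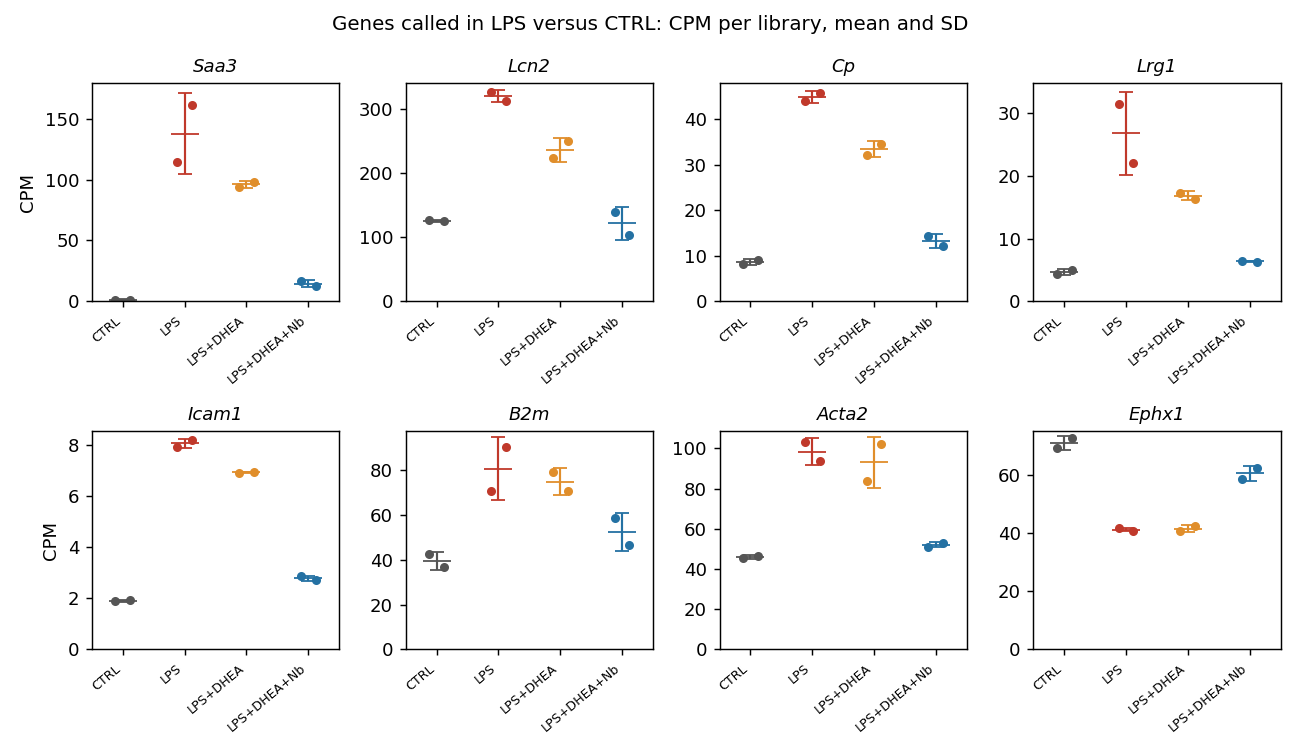
Normalised CPM of 8 genes called in LPS versus CTRL, per library (points) with group mean and SD (bars), on linear axes that start at 0, with 2 libraries in each of the 4 groups. Saa3, Lcn2, Cp, Lrg1, Icam1, B2m and Acta2 have higher means in LPS than in CTRL and Ephx1 has a lower one, and in each panel the LPS+DHEA+Nb mean lies nearer to CTRL than the LPS+DHEA mean does.

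The comparison of LPS+DHEA with LPS asks what DHEA changed after LPS. The labels give an injection after LPS only for the treated groups, so DHEA cannot be told apart from the injection itself. 5 genes differed, and in each the LPS+DHEA level lay nearer to CTRL than the LPS level did. The LPS libraries also serve in LPS versus CTRL, which favours this direction by chance. Simulated data with an LPS effect and no treatment effect gave 0 to 5 genes moving back in this way. In the test of the steps without changes, 3 genes were called in this comparison. Scd2, a fatty acid desaturase, went from 165 ± 4.11 CPM in LPS to 49.3 ± 0.935 CPM in LPS+DHEA, near its 51.8 ± 5.6 CPM in CTRL (log2 fold change -1.74, SE 0.09, adjusted p = 2.17e-05). Nupr1l went from 59.4 ± 5.91 to 175.2 ± 0.568 CPM (log2 fold change 1.56, SE 0.09, adjusted p = 2.78e-05). Arrb1 rose (1.32, adjusted p = 0.0153), and the Wnt pathway tumour suppressor Apc (-1.3, adjusted p = 0.0275) and the myosin motor gene Myo5a (-1.07, adjusted p = 0.0153) fell. These 5 genes are not members of the acute phase or cytokine lists.

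Acute phase genes had no member past the threshold over all genes and 2 lower when adjusted over the list alone, with 24 of 25 fold changes negative (median -0.36, camera adjusted p = 1.13e-11, adjusted p = 0.644 with an estimated correlation). Lrg1 had 26.8 ± 6.6 CPM in LPS and 16.8 ± 0.729 in LPS+DHEA, and Lcn2 had 320.4 ± 9.34 and 237 ± 18.5 CPM, both with an adjusted p of 1. Cp was at -0.42 and Steap4, a metalloreductase, at -0.98, with the same adjusted p. Camera also called lower the lists of interferon-stimulated genes (median -0.18, adjusted p = 0.00142, adjusted p = 0.676 with an estimated correlation) and of MHC class I and antigen processing (median -0.12, adjusted p = 0.00559, adjusted p = 0.644 with an estimated correlation). Neutrophil markers (median -0.32, adjusted p = 0.0477) and endothelial markers (median -0.2, adjusted p = 0.0477) were also called lower, each at adjusted p = 0.644 with an estimated correlation. Mitochondrially encoded transcripts were called higher (median 0.09, adjusted p = 0.0113, adjusted p = 0.676 with an estimated correlation). In these 5 lists no gene passed over all genes or adjusted over the list alone, among them Gbp7 at -0.68 and H2-D1 at -0.24. Cyp17a1 had 30.8 ± 18.9 CPM in LPS and 26.5 ± 1.69 in LPS+DHEA, Hsd3b1 had 17.5 ± 7.54 and 26.9 ± 2.45, and Insl3 had 559.7 ± 21.6 and 493.3 ± 13.3, all with an adjusted p of 1. Adgrg2 was at 0.342 ± 0.395 CPM in LPS+DHEA, from 4 and 38 counts.

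At an unadjusted p under 0.05 edgeR gave 927 genes here, fewer than the 1321 expected by chance, and fry called no list. The count of 5 was 37 with DESeq2, 20 with only the 2 groups compared in the fit and 10 without a filter on low counts, and it was 11 and 10 without CTRL replicate 1 or 2, 23 and 24 without LPS replicate 1 or 2, 13 and 15 without LPS+DHEA replicate 1 or 2, and 17 and 14 without LPS+DHEA+Nb replicate 1 or 2. Scd2 and Nupr1l stayed called in each of 18 alternatives that keep the thresholds, Arrb1 lost its call without LPS+DHEA replicate 2, and Apc and Myo5a each lost theirs in 2 fits with a library left out, and 6 lists became 11 without LPS replicate 1 and 3 without LPS+DHEA replicate 2.

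The comparison of LPS+DHEA+Nb with LPS+DHEA asks what Nb23-bi added to DHEA. It uses neither the CTRL nor the LPS libraries. Several of the genes that rose after LPS were lower with Nb23-bi, and 8 genes rose and 15 fell in all. Cp went from 33.4 ± 1.71 to 13.2 ± 1.48 CPM (log2 fold change -1.34, SE 0.12, adjusted p = 0.00264). Acta2 went from 92.9 ± 12.7 to 52.1 ± 1.35 CPM (log2 fold change -0.84, SE 0.1, adjusted p = 0.0172). Lrg1 went from 16.8 ± 0.729 to 6.36 ± 0.0788 CPM (log2 fold change -1.4, SE 0.17, adjusted p = 0.0172). Icam1 (-1.32, adjusted p = 0.0311), Lcn2 (-0.96, adjusted p = 0.0365) and the interferon-induced membrane protein gene Ifitm2 (-0.95, adjusted p = 0.0311) also fell. Olfr273 had 164 and 140 counts in LPS+DHEA and 5 and 4 with Nb23-bi. Cmtr2, an RNA cap methyltransferase, fell (-3.26, adjusted p = 0.0365), as did the actin methyltransferase Setd3 (-0.5, adjusted p = 0.0365). The calls of Lrg1, Icam1, Lcn2, Ifitm2, Cmtr2 and Setd3 each ended when 1 or more single libraries were left out. Lcn2 kept its call in 10 of the 18 alternatives that keep the thresholds.

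The rising genes included Lpl, which encodes lipoprotein lipase, from 3.15 ± 0.637 to 9.54 ± 0.241 CPM (log2 fold change 1.6, SE 0.22, adjusted p = 0.0322). Ephx1 rose from 41.6 ± 1.12 to 60.7 ± 2.73 CPM (log2 fold change 0.54, SE 0.08, adjusted p = 0.0491), and the sperm tail connection gene Spata6 rose (0.46, adjusted p = 0.0491). Apc (1.26, adjusted p = 0.0186) and Myo5a (0.83, adjusted p = 0.0322), which were lower in LPS+DHEA than in LPS, rose to 24.4 ± 0.729 and 21 ± 1.3 CPM. Spcs1, a signal peptidase subunit, rose (0.99, adjusted p = 0.00761), and lies opposite to Glt8d1 on the other strand, so with the strand setting of the counting unknown its value is uncertain. The calls of Lpl, Ephx1, Spata6, Apc, Myo5a and Spcs1 each ended when 1 or more single libraries were left out. Ephx1 kept its call in only 7 of the 18 alternatives.

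Acute phase genes had 3 of 25 lower, and 13 lower when adjusted over the list alone (median -0.8, camera adjusted p = 4.25e-19, adjusted p = 0.134 with an estimated correlation). Saa3 had 96 ± 2.94 CPM in LPS+DHEA and 14.5 ± 3.05 with Nb23-bi (log2 fold change -2.73, adjusted p = 0.0534), and was called when any 1 of the 4 CTRL and LPS libraries was left out and in 5 of the other alternatives. Cytokines and chemokines had none of 23 past the threshold over all genes, and 1 higher and 4 lower adjusted over the list alone (median -0.84, camera adjusted p = 1.88e-06, adjusted p = 0.189 with an estimated correlation), with Cxcl13 at -2.91 (adjusted p = 0.088), called without LPS+DHEA+Nb replicate 1 (-4.14), with DESeq2, without a count filter and with counts divided by 4. NF-kB targets had 1 of 26 lower and 5 adjusted over the list alone (median -0.49, camera adjusted p = 9.45e-10, adjusted p = 0.118 with an estimated correlation). Neutrophil markers had 1 of 12 lower and 3 adjusted over the list alone (median -1.95, camera adjusted p = 1.64e-06, adjusted p = 0.143 with an estimated correlation), with Lcn2 as the gene that passed. S100a8 did not pass (adjusted p = 0.249), at 107 and 34 counts in LPS+DHEA and 2 and 6 with Nb23-bi. Myoid and smooth muscle markers had 1 of 12 lower and 6 adjusted over the list alone (median -0.35, camera adjusted p = 5.81e-08, adjusted p = 0.143 with an estimated correlation). Tpm2 was at -0.69 and Cnn1 at -0.95, both with adjusted p = 0.249. Genes of MHC class I and antigen processing had none of 20 lower and 3 adjusted over the list alone (median -0.21, camera adjusted p = 2.92e-05, adjusted p = 0.201 with an estimated correlation), with H2-D1 at -0.62 (adjusted p = 0.388), called without LPS+DHEA+Nb replicate 1 (-0.85) and with DESeq2.

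Camera called 5 further lists lower, with small medians. They were Toll-like receptor 4 components (median -0.11, adjusted p = 0.018, adjusted p = 0.216 with an estimated correlation), where Cd14, an LPS co-receptor, was at -1.66 (adjusted p = 0.249), and interferon-stimulated genes (median -0.15, adjusted p = 0.00206, adjusted p = 0.566 with an estimated correlation). The others were cAMP and immediate early targets (median -0.14, adjusted p = 0.000381, adjusted p = 0.189 with an estimated correlation), glucocorticoid-responsive genes (median -0.17, adjusted p = 0.00616, adjusted p = 0.242 with an estimated correlation) and Sertoli cell markers (median -0.09, adjusted p = 0.00918, adjusted p = 0.218 with an estimated correlation). In these 5 lists only Lcn2, a glucocorticoid-responsive gene, passed over all genes, and adjusted over the list alone 1 Toll-like receptor 4 component and 1 glucocorticoid-responsive gene were lower. Leydig cell genes were called higher, with 17 of 22 fold changes positive, none past the threshold over all genes and 1 lower adjusted over the list alone (median 0.19, camera adjusted p = 3.61e-05, adjusted p = 0.216 with an estimated correlation). Cyp17a1 had 26.5 ± 1.69 CPM in LPS+DHEA and 104.5 ± 11.6 with Nb23-bi (log2 fold change 1.98, SE 0.51, adjusted p = 0.979), and Hsd3b1 had 26.9 ± 2.45 and 63.1 ± 4.92 CPM (adjusted p = 0.901). Both were called with only the 2 groups compared, Cyp17a1 also with DESeq2 and Hsd3b1 also without LPS replicate 1 or 2 (1.24 in each). Star had 19.9 ± 7.53 and 49.4 ± 18.8 CPM, and Insl3 had a log2 fold change of 0.11, both with an adjusted p of 1. Mitochondrially encoded transcripts (median 0.16, camera adjusted p = 8.7e-05, adjusted p = 0.401 with an estimated correlation) and spermatid genes (median 0.04, camera adjusted p = 0.0178, adjusted p = 0.495 with an estimated correlation) were called higher too, with no gene past the threshold over all genes or over the list alone. Adgrg2 was at 0.646 ± 0.0679 CPM with Nb23-bi (adjusted p = 1).

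At an unadjusted p under 0.05 edgeR gave 1161 genes, against 1321 expected by chance, and fry called 1 list. The count of 23 was 107 with DESeq2, 42 without a filter on low counts, 40 with only the 2 groups compared, 36 without CTRL replicate 1, 64 and 39 without LPS+DHEA+Nb replicate 1 or 2, and 13 at a log2 fold change of at least 1. Only 6 of the 23 were called again without LPS+DHEA replicate 1 and 9 without LPS+DHEA replicate 2. Of 16 called genes followed through the 18 alternatives that keep the thresholds, Cp and Acta2 alone stayed called in each, though Acta2 (-0.84) does not reach a log2 fold change of 1 in size, and 14 lists became 9 without LPS+DHEA replicate 1.

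The comparison of LPS+DHEA+Nb with LPS asks what both agents together changed, and again cannot tell the agents apart from the injection itself. 11 genes rose and 34 fell. Scd2 went from 165 ± 4.11 to 46.7 ± 0.845 CPM (log2 fold change -1.82, SE 0.09, adjusted p = 8.34e-06), and Nupr1l from 59.4 ± 5.91 to 185.3 ± 13.9 CPM (log2 fold change 1.64, SE 0.09, adjusted p = 1.12e-05), so both were again near their CTRL levels. Cp went from 44.8 ± 1.23 to 13.2 ± 1.48 CPM (log2 fold change -1.76, SE 0.12, adjusted p = 8.68e-05). Lcn2 went from 320.4 ± 9.34 to 121.9 ± 25.6 CPM (log2 fold change -1.39, SE 0.12, adjusted p = 0.00344). Saa3 fell from 137.6 ± 33.3 to 14.5 ± 3.05 CPM (adjusted p = 0.0182). Also lower were Lrg1 (-2.08), Serpina3n (-2.13), Timp1 (-1.73), Icam1 (-1.54), Acta2 (-0.92), Steap4 (-2.25), Csf2rb, a cytokine receptor subunit (-2.24), and Galnt15, a glycosyltransferase (-2.17), at adjusted p-values of 0.00077 to 0.0439. Olfr273 had 121 and 208 counts in LPS and 5 and 4 with both agents. Of the rising genes, Lpl (1.56), Ptn, which encodes the growth factor pleiotrophin (2.18), Arrb1 (1.33), Spcs1 (0.95), Rbm44 (0.59), Ephx1 (0.55) and Spata6 (0.45) passed at adjusted p-values of 0.0045 to 0.0351.

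Acute phase genes had 7 of 25 lower, and 16 adjusted over the list alone (median -1.3, camera adjusted p = 1e-27, adjusted p = 0.0717 with an estimated correlation). Cytokines and chemokines had 1 of 23 lower and 3 adjusted over the list alone (median -1.12, camera adjusted p = 1.54e-07, adjusted p = 0.099 with an estimated correlation). The risen chemokine gene Cxcl13 fell to 30 and 8 counts (log2 fold change -3.52, adjusted p = 0.0182). NF-kB targets had 1 of 26 lower and 8 adjusted over the list alone (median -0.46, camera adjusted p = 2.11e-11, adjusted p = 0.0717 with an estimated correlation). Neutrophil markers had 1 of 12 lower, Lcn2, and 5 adjusted over the list alone (median -2.39, camera adjusted p = 4.61e-08, adjusted p = 0.0895 with an estimated correlation). Myoid markers had 1 of 12 lower and 7 adjusted over the list alone (median -0.4, camera adjusted p = 5.82e-09, adjusted p = 0.0895 with an estimated correlation). Genes of MHC class I had none of 20 past the threshold over all genes and 5 lower adjusted over the list alone (median -0.41, camera adjusted p = 6.59e-10, adjusted p = 0.0895 with an estimated correlation), with H2-D1 at -0.87 (adjusted p = 0.0569), called without LPS+DHEA+Nb replicate 1 (-1.1) and in 6 other alternatives. Interferon-stimulated genes had none of 46 past it and 2 adjusted over the list alone (median -0.46, camera adjusted p = 5.82e-09, adjusted p = 0.336 with an estimated correlation).

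Toll-like receptor 4 components (median -0.22, camera adjusted p = 0.000459), cAMP targets (median -0.17, camera adjusted p = 1.84e-05), glucocorticoid-responsive genes (median -0.14, camera adjusted p = 0.000343) and endothelial markers (median -0.28, camera adjusted p = 0.000893) were also called lower. With an estimated correlation these gave adjusted p = 0.0895, adjusted p = 0.099, adjusted p = 0.152 and adjusted p = 0.099. Over all genes only Lcn2 of the glucocorticoid-responsive genes passed, and adjusted over the list alone 1, 4, 3 and 0 genes were lower. Sertoli cell markers (median -0.12, camera adjusted p = 0.0362), the blood-testis barrier (median -0.09, camera adjusted p = 0.0304) and spermatogonial markers (median -0.11, camera adjusted p = 0.0221) were called lower, with adjusted p = 0.285, adjusted p = 0.2 and adjusted p = 0.142 under an estimated correlation. None of their genes passed over all genes, and adjusted over the list alone 1, 0 and 1 were lower. Leydig cell genes were called higher (median 0.17, camera adjusted p = 0.0221, adjusted p = 0.341 with an estimated correlation), with none past the threshold over all genes and 3 higher and 2 lower adjusted over the list alone. Hsd3b1 was at 1.85 (adjusted p = 0.246), Cyp17a1 at 1.76 (adjusted p = 0.659) and Insl3 at -0.07 (adjusted p = 0.941). Hsd3b1 and Cyp17a1 were both called with DESeq2 and without LPS replicate 1 (1.47 and 2.59), and Hsd3b1 also without LPS replicate 2 (2.37). Meiotic prophase genes (median 0.03, camera adjusted p = 0.0403, adjusted p = 0.409 with an estimated correlation), spermatid genes (median 0.04, camera adjusted p = 0.0228, adjusted p = 0.461 with an estimated correlation) and mitochondrially encoded transcripts (median 0.24, camera adjusted p = 5.82e-09, adjusted p = 0.285 with an estimated correlation) were called higher, with no gene past the threshold over all genes and 1 mitochondrial transcript higher over the list alone.

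At an unadjusted p under 0.05 edgeR gave 1732 genes, against 1321 expected by chance, and fry called 5 lists. The count of 45 was 204 with DESeq2, 87 without a filter on low counts, 69 at an adjusted p under 0.10, 19 with only the 2 groups compared, 74 without LPS replicate 1 and 88 without LPS+DHEA+Nb replicate 1. Scd2, Nupr1l, Cp, Lrg1 and Acta2 stayed called in each of 18 alternatives that keep the thresholds, the calls of Saa3, Cxcl13, Serpina3n, Timp1, Steap4, Csf2rb, Galnt15, Lpl, Ptn, Rbm44, Ephx1 and Spata6 each ended when 1 or more single libraries were left out, and 18 lists became 10 without LPS replicate 2.

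The 78 genes called in LPS versus CTRL were then followed into the treated groups. In LPS+DHEA, 5 of them moved back, that is, were called in the opposite direction against LPS, and 34 were still called against CTRL. The median gene kept 78.7% of its LPS change on the log2 scale. In LPS+DHEA+Nb, 31 moved back, 26 of the genes raised by LPS and 5 of those lowered, and 3 were still called against CTRL. The median gene kept 29.1%. None of the 78 moved further in either group. In comparisons that share the LPS libraries some return arises by chance. Over 25 simulated data sets with an LPS effect and no treatment effect, a median of 1 gene moved back, with 0 to 5 across sets, and the median gene kept 96.8% (92 to 100.1). With no effect at all a median of 0 genes moved back, with 0 to 4 across sets. The simulated LPS effect was set to the observed means of the called genes, and genes were drawn independently. Chance return may therefore be larger than simulated. Independent lists of these sizes would share 0.0085 genes in LPS+DHEA and 0.092 in LPS+DHEA+Nb. Across genes, which are not independent replicates, the covariance of the fold changes was -0.4028 in LPS+DHEA and -0.4673 in LPS+DHEA+Nb, against a simulated -0.2218 (-0.2496 to -0.1975). The correlations were -0.495 and -0.562 against a simulated -0.489 (-0.523 to -0.446). The correlation of LPS+DHEA thus lay within the range simulated without a treatment effect, while the covariances of both groups lay outside theirs. Part of the return may come from the shared libraries. Splitting the LPS libraries avoids the sharing but leaves a single library for each comparison. With LPS library 1 for the call and the other for the return, 52 genes were called, of which 3 moved back in LPS+DHEA and 20 in LPS+DHEA+Nb. With library 2 for the call, 100 genes were called, of which 6 and 20 moved back. The covariances without a shared LPS library were smaller, at -0.0836 and -0.0909 in LPS+DHEA and -0.1804 and -0.1673 in LPS+DHEA+Nb, with correlations of -0.055, -0.06, -0.117 and -0.108. Most of the covariance in LPS+DHEA thus went with the shared libraries. The simulated libraries may therefore vary less than the real ones, and 0 to 5 genes may be too narrow a range for chance return. The count of 5 was 20 with DESeq2, 23 and 20 without LPS replicate 1 or 2, 2 and 3 without LPS+DHEA replicate 1 or 2, and 11 and 10 without LPS+DHEA+Nb replicate 1 or 2, and the count of 31 was 121 with DESeq2 and 62 without LPS replicate 1.

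**Figure D3:**
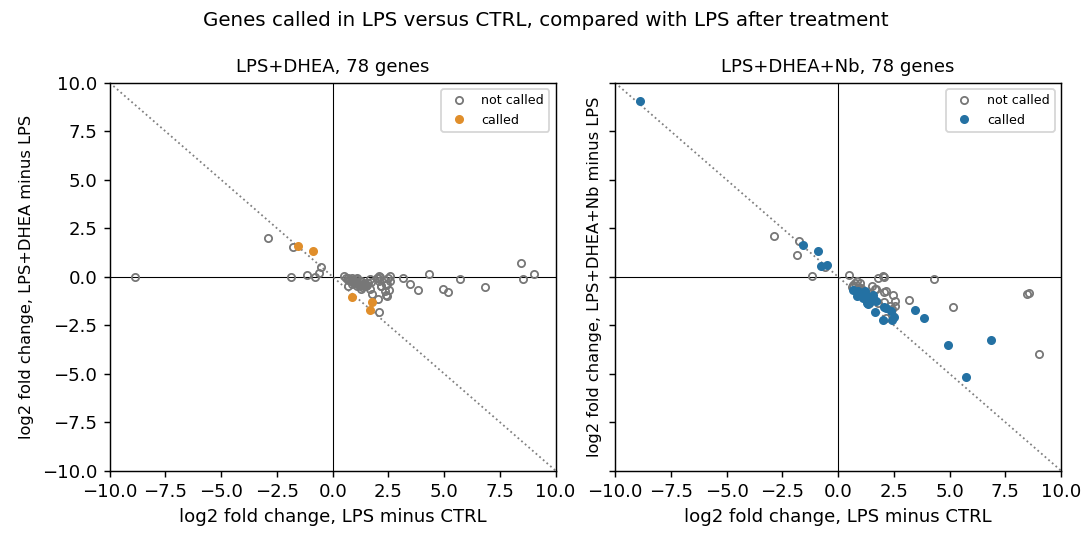
Log2 fold change of LPS against CTRL (horizontal axis) and of the treated group against LPS (vertical axis) for the 78 genes called in LPS versus CTRL, with LPS+DHEA on the left and LPS+DHEA+Nb on the right, filled points for genes called on the vertical axis and a dotted line for full return. 5 genes are filled on the left and 31 on the right, and fitted values of genes near 0 counts in a group depend on the prior count.

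Against CTRL, 36 genes were higher and 4 lower in LPS+DHEA, and 4 were higher and 4 lower in LPS+DHEA+Nb. Saa3 (log2 fold change 6.33, adjusted p = 0.00392), Serpina3n (3.17, adjusted p = 0.0115), Timp1 (3.12, adjusted p = 0.00176), Cp (1.95, adjusted p = 0.000135), Icam1 (1.87, adjusted p = 0.00262), Lrg1 (1.85, adjusted p = 0.00253) and Acta2 (1.02, adjusted p = 0.00262) were higher in LPS+DHEA than in CTRL. In LPS+DHEA+Nb versus CTRL the same genes did not pass, with Saa3 at 3.6 (adjusted p = 0.0656), Timp1 at 1.74 (adjusted p = 0.0732), Serpina3n at 1.71 (adjusted p = 0.239) and Cp at 0.62 (adjusted p = 0.235). Ephx1 and Ncoa4 were lower in LPS+DHEA than in CTRL, and Ncoa4 was also lower in LPS+DHEA+Nb (-1.14, adjusted p = 0.00209). The count of 40 for LPS+DHEA was 173 with DESeq2, 80 without a filter on low counts, 62 at an adjusted p under 0.10, 61 with only the 2 groups compared, and 64 and 65 without LPS+DHEA+Nb replicate 1 or 2. The count of 8 for LPS+DHEA+Nb was 76 with DESeq2, 17 without a filter on low counts, 27 and 27 without CTRL replicate 1 or 2, 13 without LPS replicate 1, and 37 and 31 without LPS+DHEA+Nb replicate 1 or 2.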

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

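Counts divided by 4 and overlapping genes summed were chosen after seeing the data, and the other alternatives before. The cause of a changed count was not tested unless stated. Without a filter on low counts, more genes were tested, and the counts of called genes were 140 in LPS versus CTRL (78 as reported), 10 in LPS+DHEA versus LPS (5), 42 in LPS+DHEA+Nb versus LPS+DHEA (23), 87 in LPS+DHEA+Nb versus LPS (45), 80 in LPS+DHEA versus CTRL (40) and 17 in LPS+DHEA+Nb versus CTRL (8). DESeq2 gave 281, 37, 107, 204, 173 and 76 in the same order. With only the 2 groups compared, and so fewer samples, LPS+DHEA versus LPS gave 20, LPS+DHEA+Nb versus LPS+DHEA 40, LPS+DHEA+Nb versus LPS 19 and LPS+DHEA versus CTRL 61. At an adjusted p under 0.10, a looser threshold, LPS versus CTRL gave 122, LPS+DHEA+Nb versus LPS 69 and LPS+DHEA versus CTRL 62. A log2 fold change of at least 1 left 13 genes in LPS+DHEA+Nb versus LPS+DHEA. DESeq2 gave 20 and 121 genes moved back in LPS+DHEA and LPS+DHEA+Nb (5 and 31 as reported). With LPS library 1 for the call and the other for the return the counts were 3 and 20, and with library 2 for the call the second was 20. Camera with an estimated correlation called 0 lists in each of the 4 comparisons, and fry called 7, 0, 1 and 5. The other counts of genes, lists and genes moved back, under DESeq2 size factors, library size alone, limma-voom, the CPM minimum, counts divided by 4 and overlapping genes summed, stayed within 1.5 times.

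With 1 library left out in turn, its partner is assumed to vary like the other groups. The counts of called genes then ranged from 66 to 118 in LPS versus CTRL, 10 to 24 in LPS+DHEA versus LPS, 16 to 64 in LPS+DHEA+Nb versus LPS+DHEA, 43 to 88 in LPS+DHEA+Nb versus LPS, 27 to 65 in LPS+DHEA versus CTRL and 8 to 37 in LPS+DHEA+Nb versus CTRL. Of the genes reported as called, the fits called again 33 to 77 of 78, 3 to 5 of 5, 6 to 20 of 23, 26 to 41 of 45, 12 to 40 of 40 and 6 to 8 of 8. Lists called ranged from 11 to 19, 3 to 11, 9 to 15 and 10 to 19 in the 4 comparisons, and genes moved back from 2 to 23 in LPS+DHEA and 22 to 62 in LPS+DHEA+Nb. No called gene that was named changed direction. Of 18 values for each such gene, the call ended in 92 of 522 in LPS versus CTRL, 6 of 90 in LPS+DHEA versus LPS, 65 of 288 in LPS+DHEA+Nb versus LPS+DHEA and 84 of 432 in LPS+DHEA+Nb versus LPS. Named genes that were not called gained a call in 17 of 336 values in LPS versus CTRL, 0 of 179 in LPS+DHEA versus LPS, 25 of 233 in LPS+DHEA+Nb versus LPS+DHEA and 14 of 90 in LPS+DHEA+Nb versus LPS, and some reversed with single libraries left out. The log2 fold changes ranged from -0.1 to 0.02 for Insl3, -0.06 to 0.29 for Star, -0.26 to 0.83 for Il1b and -0.77 to 0.87 for Adgrg2 in LPS versus CTRL, with 0 for Insl3, -0.01 for Star and -0.02 for Adgrg2 in between, and from -0.74 to 0.6 for Cyp17a1 in LPS+DHEA versus LPS. With overlapping genes summed, Cx3cr1 was at 0.17 in LPS versus CTRL and -0.13 in LPS+DHEA+Nb versus LPS, where its locus also holds the counts of other genes. Tnf, Tlr4 and Adgrg2 had too few counts for a value under some alternatives.

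The replicate numbers did not pair the libraries, since same-numbered libraries deviated from their group means with correlations of -0.033 to 0.031. With the replicate block, the counts of called genes were 62, 5, 16, 47, 29 and 8 in the order above, the lists 14, 7, 14 and 18, and the genes moved back 3 in LPS+DHEA and 30 in LPS+DHEA+Nb. Of the 5 genes reported in LPS+DHEA versus LPS, 4 were called again with the block, and Apc was not.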

Other observations

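The 6 tests of explanations in this part were chosen after the results were seen, and the comparisons by edgeR before. The list of monocyte and macrophage markers did not pass in LPS+DHEA+Nb versus LPS, with 14 of 24 fold changes positive and 10 negative (median 0.09, camera adjusted p = 0.253). Marco, outside that list, kept a mean of 4.78 ± 3.09 CPM in LPS+DHEA+Nb, near its 5.2 ± 1.39 in LPS (log2 fold change -0.12, adjusted p = 0.997, edgeR), and Tlr2, of the Toll-like receptor 4 list, had 1.75 ± 0.00827 CPM in LPS and 1.73 ± 0.0919 in LPS+DHEA+Nb (adjusted p = 0.999). Cd163, a haemoglobin scavenger receptor on the macrophage list, fell from 2.46 ± 0.646 in LPS to 0.315 ± 0.156 CPM in LPS+DHEA+Nb (log2 fold change -2.95, adjusted p = 0.0318). Cd209f, a C-type lectin outside the list, rose from 0.563 ± 0.0947 to 4.68 ± 3.22 CPM (log2 fold change 3.05, adjusted p = 0.0378), from 153 and 441 counts in the 2 libraries with both agents. The calls of Cd163 and Cd209f ended in 4 and 7 of the 8 fits with a library left out. Cx3cr1, a chemokine receptor of resident macrophages, had 3.13 ± 0.364, 1.23 ± 0.177, 1.33 ± 0.426 and 3.51 ± 0.0611 CPM in CTRL, LPS, LPS+DHEA and LPS+DHEA+Nb and was not called by edgeR in any of the 6 comparisons, though DESeq2 called it in LPS versus CTRL and in LPS+DHEA+Nb versus LPS and versus LPS+DHEA.

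3 genes changed by LPS were still called in LPS+DHEA+Nb versus CTRL. Ncoa4 stayed at 61.5 ± 1.11 CPM, against 135.7 ± 17.5 in CTRL and 60.7 ± 0.2 in LPS. Apc was at 24.4 ± 0.729 CPM, against 7.32 ± 1.2 in CTRL and 25.1 ± 1.88 in LPS. Nol8, which encodes a nucleolar protein and was chosen after its values were seen, was higher than in CTRL in LPS (log2 fold change 0.5, adjusted p = 0.0259) and in LPS+DHEA+Nb (0.59, adjusted p = 0.0337).

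Genes changed by LPS lay nearer to CTRL in LPS+DHEA+Nb. Chance values of the shared LPS libraries are argued against, since in LPS+DHEA+Nb versus LPS+DHEA, which uses no LPS or CTRL library, 71 of the 78 genes (91%) lay on the side opposite to their LPS change, and 67 to 70 did in the 4 pairings of single libraries. A rise in the share of germ cells large enough for these changes, which would lower transcripts of every other cell type alike, is argued against too. The median of 100 markers of Leydig, Sertoli, peritubular myoid, endothelial and macrophage cells was -0.01 (95% bootstrap interval -0.06 to 0.07, 10000 draws), while genes raised by LPS had a median of -0.61 (-0.8 to -0.51). By list, the medians were -0.35 for myoid, -0.09 for Sertoli, -0.04 for endothelial, 0.17 for macrophage and 0.19 for Leydig genes. None of these lists passed by camera with an estimated correlation (adjusted p = 0.143, 0.218, 0.401, 0.242 and 0.216). With the preset correlation, camera called myoid and Sertoli markers lower and spermatid genes higher, as a larger germ cell share would give. It called Leydig genes higher, against that. A small rise in the germ cell share stays open. A weaker response to LPS in these 2 libraries, for a reason other than treatment, stays open and untested, as does an effect of the agents, since no group received the agents with another exposure to LPS.

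5 genes were called in LPS+DHEA versus LPS, and each was also called in LPS versus CTRL. Counts moved between overlapping genes are argued against, since for 5 of the 5 genes the overlapping genes held at most 1.7% of the change. For Apc and Myo5a, a shift of the 2 LPS libraries alone was tested in LPS+DHEA+Nb versus LPS+DHEA, which uses no LPS library. There 2 of these 2 genes were called. They were the only ones of the 5 called there and were picked after that was known, so the outcome was fixed and no conclusion is drawn. Values that shift in any pair of libraries were not tested for Apc and Myo5a. For Scd2 and Nupr1l, values that shift in any pair of libraries whatever their group stay open. Among genes above 2 CPM, 8, with Scd2 and Nupr1l among them, stood apart by over 0.7 on the log2 scale in the pair of LPS libraries from the other 6, and 2 of 24 pairs across groups had as many (4, 4 and 3 at 3 other settings of mean and gap). Scd2 and Nupr1l stood apart by 1.58 and 1.4, and pairs across groups with gaps as large as these were not counted. Arrb1, apart by 0.66, fell outside this scan and was not tested.

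Cyp17a1 and Hsd3b1 had lower means in LPS and LPS+DHEA without passing the test with all 8 libraries, and were called in LPS versus CTRL with DESeq2 and with LPS replicate 1 left out (-2.91 and -1.37). A loss of Leydig cells as large as the change of Hsd3b1 (-1.75) was tested on the rest of the Leydig list. The other 20 Leydig genes had a median of -0.02 in LPS versus CTRL (95% bootstrap interval -0.12 to 0.19, between genes and not libraries). Genes raised by LPS, and genes of the list that other testis cells may express too, could hide a loss in this median. Whether the list is restricted to Leydig cells was not tested, so the median does not decide. In the whole list 3 genes were higher and 5 lower when adjusted over the list alone. Lhcgr was at -1.08 (adjusted p = 0.115, edgeR), while the Leydig cell hormone gene Insl3, at -0.04, showed no fall as large as that of Hsd3b1. A loss of Leydig cells, a chance difference between libraries and a lower expression per cell stay open.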
